A study of Homo sapiens with 12 samples.

How the data were processed

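RNA of the Merkel cell carcinoma line MKL-1 was sequenced as 12 polyA-selected libraries, 3 for each of 4 groups: vehicle or 3 µM EPZ011989, for 6 or 12 days. Groups and replicate numbers come from the sample titles. The labels do not say whether libraries of 1 group came from separate cultures.

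The deposited files hold, per library, estimated counts per transcript (Salmon's expected counts of reads), made with Salmon 1.2.0, per the submitters' processing notes, which also name FastQC, DESeq2 and the build hg38. A further table of the whole series holds a normalized gene signal that the authors made. The exact normalization of that table is not given in the sources used here.

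Each library's table lists 179883 transcripts, of which 168219 (93.5%) were matched by identifier to a gene of the GRCh38 annotation used for names and coordinates. Estimated reads were summed per gene and rounded to whole numbers, giving 35347 genes. Transcripts with no matched gene held 3.08 to 3.58% of a library's reads and were left out. Because some genes are summed only in part, each gene's level was set against the authors' table. Of the 15024 tested genes 13658 lay between 0.8 and 1.25 times the authors' level relative to the median gene, 799 lay below, 44 above, and 523 had no matching entry. A fold change from the authors' table is on the log2(value + 1) scale, which understates changes of low genes.

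Genes were kept by edgeR's filterByExpr defaults on the 4 groups and scaled by TMM. The main test was edgeR 4.0.16 (R 4.3.3), quasi-likelihood, two-sided, on all 12 libraries in a single fit of the 4 groups, with Benjamini-Hochberg adjusted p under 0.05. The 4 contrasts were treatment at day 6, treatment at day 12, the difference of these effects, and day 12 against day 6 in vehicle. A gene's standard error is its log2 fold change divided by the square root of the edgeR F statistic. The prior degrees of freedom were 5.89 and the common biological coefficient of variation 10.1%.

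Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 tested genes, adjusted over the lists, and again with an estimated correlation and with fry. The 30 lists, fixed before the data were examined, covered PRC2 and PRC1 subunits, other chromatin regulators, HOX genes, other developmental transcription factors, otic and hair cell genes, Merkel cell markers, neuroendocrine secretory genes, neuronal genes, keratinocyte markers, MHC class I and class II presentation, interferon response, NK and T cell ligands, proliferation, cell cycle inhibitors, p53 targets, BCL2 family and caspases, the Notch, Wnt and TGF-beta pathways, mesenchymal genes, cancer-testis genes, stress response, heat shock, cholesterol synthesis, mitochondrial mRNAs, and fibroblast, leukocyte and endothelial markers. Some genes stand in several lists, such as PAX2 in the otic and the developmental lists. ALX4, E2F2 and ID3 were matched to no gene here.

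Named genes followed a rule fixed before the data were examined. For each treatment contrast it took the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM in the higher group and all treated libraries on the same side of all vehicle libraries. It added up to 4 members of each list with the smallest p, and a few genes fixed by name, among them EZH2, EZH1, EED and SUZ12. Some genes that the rule took are not reported here. For the other 2 contrasts it took 6 in each direction. For a gene with no read in a group, the change is a bound against a floor of 3 counts per library. For a gene with few reads in a group, the ratio of summed reads is given with an exact 95% interval, where the rule as fixed had foreseen a bound. Floors and intervals cover counting error only.

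The scripts were tested on simulated counts for 15024 genes with 200 changed. The changed genes had a mean of at least 1 CPM, as many were raised as lowered, and the spread was that of the fit. Far more genes were called in the real data, so the recoveries and false calls need not carry over. At day 6 edgeR recovered 86% of the 2-fold and 91% of the 4-fold changes, with 5 false calls. At day 12 it recovered 89% and 94%, with 4 false calls. The same test recovered 73% and 88% for the difference between days, with 2 false calls, and 76% and 94% in vehicle, with 3.

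Alternatives were DESeq2 1.42.0 size factors, library totals without TMM, no low-count filter, a stricter filter, the DESeq2 test, only the libraries of a contrast, transcript lengths as an offset, limma on the authors' table with pseudocounts of 1 and 5, a fold limit, a stricter threshold, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were completely summed genes only, the list counts without replicate 1 of the day 12 vehicle group, genes at 10 CPM or more in vehicle or over all libraries, genes at least 2-fold from the median gene, and the tests of neighbouring genes. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of 4.21 to 17.0.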

Results

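The transcriptome of MKL-1, an established Merkel cell carcinoma line that carries Merkel cell polyomavirus, was measured by sequencing of polyA-selected RNA. Cells had received 3 µM EPZ011989, a small molecule that blocks the methyltransferase activity of EZH2, or ethanol at 1%, its vehicle, over 6 or 12 days. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3 at silent genes. Each of the 4 groups held 3 libraries. The 12 libraries contained about 15995000 to 20866400 estimated reads each, and 15024 genes had enough reads to be tested. At these depths 3 reads of a gene in 1 library corresponded to 0.148 to 0.194 CPM, the count scaled to library size. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. All group values below are means ± SD of 3 libraries in CPM, and log2 fold changes are given ± their standard error.

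The first principal component of log2 CPM held 63.1% of the variance and separated the treated from the vehicle libraries at both days, with the treated day 12 libraries farthest out. More genes were detected in treated cells. At least 10 reads were found for 13605 to 13950 genes per vehicle library, 14020 to 14507 per treated library at day 6 and 14616 to 14829 at day 12. Replicate 1 of the day 12 vehicle group stood apart from the other 2 on the third component (-47.4 against -14.3 and 5.84), and list counts without it are given where they moved by over 1.5 times.

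The first comparison asked which transcripts change when EZH2 is inhibited for 6 days. PAX2, a paired box transcription factor of ear and kidney development (chromosome 10, 100735603 to 100829941, GRCh38), rose from 3.57 ± 0.193 CPM in vehicle to 39.2 ± 1.31 CPM in treated cells, a log2 fold change of 3.45 ± 0.13 (edgeR adjusted p = 8.44e-11), and CDH23, the cadherin of hair cell tip links (chromosome 10, 71396934 to 71815947), from 57.7 ± 2.62 to 339 ± 5.09 CPM. Genes of cell division fell by a smaller amount, with MYBL2, a transcription factor of late cell cycle genes, going from 571 ± 4.11 to 337 ± 7.68 CPM (-0.76 ± 0.05 log2). In all, 2575 genes rose and 2558 fell, but among those that changed at least 2-fold 1067 rose and 104 fell. With library totals in place of TMM 2826 of 4874 called genes (58.0%) rose.

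**Figure D1:**
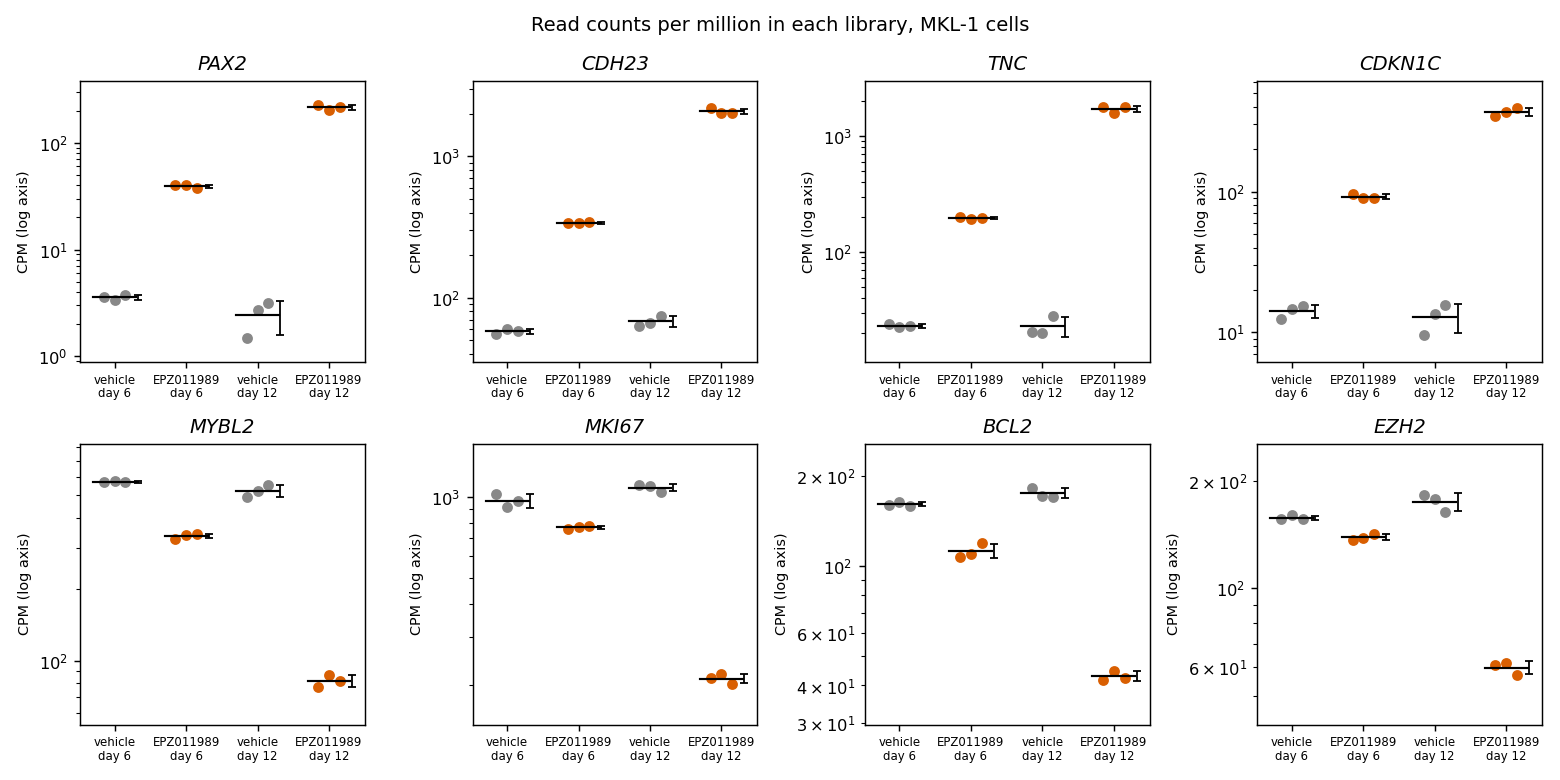
Read counts of 8 genes in each of the 12 libraries, in CPM on a log axis whose range differs between panels. Points are libraries, horizontal lines group means and error bars SDs of 3 libraries. PAX2, CDH23, TNC and CDKN1C lie higher in treated libraries at both days, and MYBL2, MKI67, BCL2 and EZH2 lie lower, by more at day 12, when the EZH2 mean was 60.0 CPM against 174 CPM in vehicle.

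The transcripts of the drug's target complex changed little at day 6. EZH2 itself (chromosome 7, 148807383 to 148884321) went from 157 ± 2.36 to 139 ± 2.84 CPM, a log2 change of -0.18 ± 0.05 (edgeR adjusted p = 0.0112). Its paralogue EZH1 (0.09 ± 0.08 log2) and the core subunits SUZ12 (-0.12 ± 0.08) and EED (-0.25 ± 0.15) did not pass the test (edgeR adjusted p of 0.449, 0.274 and 0.235). The summed reads of EED reached only 0.578 of the authors' gene level, so its value covers part of its transcripts. Of 13 PRC2 genes 1 rose and 3 fell (as many adjusted over the list alone), the riser being JARID2, an accessory subunit that recruits the complex (0.66 ± 0.05 log2). Of 24 genes of Polycomb repressive complex 1, 7 rose and 3 fell (as many adjusted over the list alone), with BMI1 at 1.17 ± 0.07, RYBP at 0.89 ± 0.06 and PHC2 at -0.49 ± 0.06 log2. Of 16 other chromatin regulators, 1 rose and 5 fell (as many adjusted over the list alone). Besides enzymes acting on H3K27 and H3K4, this list holds H3K36 methyltransferase and chromatin remodelling genes. The fallers were KMT2D, the H3K36 methyltransferase gene NSD2 (-0.47 log2) and the remodelling genes SMARCA4, ARID1A and ARID1B.

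The largest rises at day 6 were in genes with almost no reads in vehicle. COL19A1, a collagen gene (chromosome 6, 69866571 to 70209976), had no read in any day 6 vehicle library and 5.39 ± 1.16 CPM in treated cells, at least 33.2-fold higher when 3 reads per library are taken as the floor. On the same floor BCAM, a laminin-binding surface protein gene, was at least 17.6-fold higher and the sodium leak channel gene NALCN at least 6.39-fold higher. NDNF, POPDC3 and ITGB8, an integrin subunit gene, each had 1 read over the day 6 vehicle group, with ratios of 119 (95% counting interval 20.8 to 4722), 75.9 (95% counting interval 13.2 to 3038) and 68.6 (95% counting interval 11.9 to 2751). The ratio was 71.2 (95% counting interval 19.3 to 594) for GNG7, a G protein subunit gene, 56.3 (95% counting interval 25.6 to 155) for BEND7 and 50.2 (95% counting interval 19.3 to 186) for RGPD1, which has near-identical copies and may share reads with them. FMN1, a formin of the actin cytoskeleton, rose from 0.218 ± 0.164 to 16.6 ± 2.12 CPM (6.22 ± 0.39 log2). CHL1, a neural adhesion molecule, went from 0.108 ± 0.00243 to 4.55 ± 0.671 CPM and TSPOAP1 from 0.0365 ± 0.0316 to 2.15 ± 0.517 CPM, but their summed reads stood at 1.51 and 0.655 times the authors' level. In the authors' table their log2 fold changes were 2.61 and 4.42.

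The largest falls at day 6 included immunoglobulin heavy chain genes, which some Merkel cell carcinomas transcribe. IGHG4 went from 84.5 ± 8.77 to 13.2 ± 1.80 CPM (-2.67 ± 0.11 log2), IGHG3 from 25.1 ± 2.60 to 5.41 ± 0.989 and IGHG2 from 4.46 ± 0.775 to 0.965 ± 0.247 CPM. These genes are near-identical copies, so the split of reads between them is uncertain. CD79B, which encodes a B cell receptor subunit, fell from 8.91 ± 0.270 to 1.91 ± 0.403 CPM (edgeR adjusted p = 7.20e-05). DCT, a melanin synthesis enzyme gene, fell by 2.12, the transporter gene SLC6A18 by 2.03, TGM7 by 1.91 and HMCN2, a hemicentin gene, by 1.83 on the log2 scale. DGCR6 was at 12.6 ± 6.14 and 3.17 ± 0.169 CPM, with a wide spread in vehicle, and it has a close paralogue. The histone genes H4C15 and H2BC9 are members of multigene families and their values are uncertain. H4C15 had no read in treated cells at day 6 and was at least 14.4-fold lower, and H2BC9 fell by 1.89 on the log2 scale. HSPA1B, a near-identical copy of HSPA1A, held 0.0506 of the authors' level, and its log2 fold change of -2.81 stood against -0.20 in the authors' table.

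Among the gene lists, otic placode and inner ear hair cell genes rose as a group at day 6. Of 45 tested, 22 rose and 5 fell (23 and 7 adjusted over the list alone), with a median log2 fold change of 0.66 (camera adjusted p = 2.33e-14, adjusted p = 0.0108 with an estimated correlation). The fallers were CALB2 (-1.20), PCDH15 (-0.93), INSM1 (-0.58), COCH (-0.24) and POU4F3 (-0.19 log2), and ATOH1 (-0.04) did not pass edgeR. Besides PAX2 and CDH23, the risers included CIB2, a subunit of the hair cell transduction complex, which rose from 3.21 ± 0.465 to 36.5 ± 2.09 CPM. Proliferation genes went the other way, since of 55 tested 0 rose and 47 fell (0 and 51 adjusted over the list alone), with a median of -0.36 log2 (camera adjusted p = 3.60e-16, but adjusted p = 0.128 with an estimated correlation). CDC25A, a phosphatase of S phase entry, fell by 0.66, FOXM1, a transcription factor of mitotic genes, by 0.59 and the replication helicase gene MCM7 by 0.40 on the log2 scale. Other lists had medians near the otic one, among them TGF-beta and BMP (0.70), Wnt (0.67), Notch (0.65) and mesenchymal genes (0.61 log2). Of the genes raised at least 2-fold at day 6, 44.2% had under 1 CPM in vehicle, against 13.1% of all genes. No list was set against genes of like vehicle expression. A general rise of low genes is therefore not told apart from a rise of the otic list.

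Developmental transcription factors outside the HOX clusters also rose on balance at day 6. Of 80 tested, 32 rose and 11 fell (36 and 13 adjusted over the list alone) (camera adjusted p = 1.70e-04, adjusted p = 0.0790 with an estimated correlation), among them SIX4 (1.86 ± 0.09 log2) and DLX5 (3.56 ± 0.25). Of 41 mesenchymal and adhesion genes 17 rose and 3 fell (as many adjusted over the list alone) (camera adjusted p = 1.39e-05, adjusted p = 0.0790 with an estimated correlation). The matrix glycoprotein gene TNC rose from 23.1 ± 0.823 to 197 ± 3.45 CPM, COL6A1 by 2.41, the laminin gene LAMC1 by 1.39 and THBS1 by 0.66 log2. Of 53 neuronal differentiation and axon genes 23 rose and 9 fell (as many adjusted over the list alone) (camera adjusted p = 0.0143, adjusted p = 0.128 with an estimated correlation). The tubulin gene TUBB2B rose from 5.62 ± 1.58 to 92.1 ± 4.89 CPM and CNTN2 by 1.07 log2, while the neurofilament gene NEFL fell by 0.63. Of 23 Notch pathway genes 12 rose and 4 fell (as many adjusted over the list alone) (camera adjusted p = 0.0134, adjusted p = 0.246 with an estimated correlation), with the receptor gene NOTCH2 at 1.60 ± 0.05 and the target gene HES1 at 2.60 ± 0.25 log2. The p-values of these 4 lists stand below the threshold only at the preset correlation.

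The other tested lists did not pass camera at day 6. Of 26 HOX genes 10 rose and 7 fell (as many adjusted over the list alone), with HOXD13 at 4.88 ± 0.51, HOXC13 at 2.13 ± 0.21 and HOXA9 at -0.66 ± 0.05 log2. Of 33 Wnt pathway genes 13 rose and 3 fell (as many adjusted over the list alone) and of 29 TGF-beta and BMP genes 12 rose and 3 fell (13 and 3 adjusted over the list alone). The ligand gene WNT9A rose by 3.39, LEF1 by 2.52 and SMAD6 by 2.31 log2, while BMP7 fell by 1.33. Of 13 cell cycle inhibitor genes 3 rose and 4 fell (3 and 5 adjusted over the list alone). CDKN1C, which encodes p57 (chromosome 11, 2883213 to 2885773), rose from 14.2 ± 1.53 to 92.2 ± 3.46 CPM and CDKN1A by 0.57 log2, while CDKN2C fell by 0.87. Of 32 p53 target genes 7 rose and 6 fell (as many adjusted over the list alone), and of 26 BCL2 family and caspase genes 7 rose and 3 fell (as many adjusted over the list alone). Among the latter, HRK, a pro-apoptotic member, rose by 2.07 and BCL2, the survival factor, fell by 0.52 on the log2 scale.

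Lineage genes of the tumour moved both ways at day 6. Of 25 Merkel cell markers and lineage factors 5 rose and 12 fell (as many adjusted over the list alone), with the somatostatin receptor gene SSTR2 rising by 1.37 and ISL1 falling by 0.51 on the log2 scale. Of 29 neuroendocrine secretory genes 12 rose and 4 fell (12 and 6 adjusted over the list alone), with CADPS, a factor of dense-core vesicle release, at 1.70 ± 0.05 and CHGA at 0.57 ± 0.09 log2. Of 18 MHC class I presentation genes 2 rose and 3 fell (as many adjusted over the list alone). The peptide transporter gene TAP1 rose from 2.61 ± 0.618 to 11.3 ± 1.05 CPM. Of 5 class II genes 1 rose and 0 fell (as many adjusted over the list alone), of 26 interferon response genes 7 rose and 1 fell (6 and 1 adjusted over the list alone), and of 9 ligands of NK and T cells 3 rose and 0 fell (as many adjusted over the list alone). Without replicate 1 of the day 12 vehicle group, which shares the estimate of the spread, 10 neuroendocrine secretory and 2 interferon response genes fell. HERC5 rose by 1.43 and the checkpoint ligand gene CD276 by 2.17 log2, while OAS3 fell by 0.50. In the list of unfolded protein and integrated stress response genes 3 rose and 11 fell (3 and 12 adjusted over the list alone) of 26, in the heat shock list 2 rose and 5 fell (as many adjusted over the list alone) of 12, and in the cholesterol synthesis list 2 rose and 9 fell (as many adjusted over the list alone) of 24. The serine synthesis gene PSAT1 rose by 0.78 and ATF5 fell by 0.93 on the log2 scale.

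Markers of other cell types gave no list call at day 6. Of 6 fibroblast markers 1 rose and 0 fell (as many adjusted over the list alone), of 6 leukocyte markers 0 rose and 1 fell (as many adjusted over the list alone), of 5 endothelial markers 1 rose and 0 fell (as many adjusted over the list alone) and of 7 keratinocyte markers 3 rose and 0 fell (as many adjusted over the list alone). The leukocyte marker that fell was CD79B. Of 13 mitochondrially encoded mRNAs 3 rose and 0 fell (0 and 0 adjusted over the list alone). The 4 tested cancer-testis genes were too few for a list test, and none of TDRD1, SYCP3, PRAME and MAEL passed edgeR (0.73, 0.68, -0.18 and -0.06 log2). Median and mean log2 fold change differed in sign for the PRC1 list (-0.00294 against 0.11), keratinocyte markers (-0.11 against 0.68), class I presentation (-0.01 against 0.18) and p53 targets (-0.07 against 0.01).

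All counts of this comparison rest on edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjusted p under 0.05. With transcript lengths as an offset the 5133 called genes became 3238, and at an adjusted p under 0.01 they became 3402. The 6 lists past the threshold became 1, the otic list, when the correlation between genes was estimated from the data.

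The second comparison asked the same after 12 days. By then cell division genes were several-fold lower in treated cells and sensory organ genes were higher by more than at day 6. MKI67, the proliferation marker, went from 1080.2 ± 31.0 to 211 ± 8.71 CPM (-2.35 ± 0.05 log2, edgeR adjusted p = 3.44e-14) and MYBL2 from 524 ± 29.7 to 82.1 ± 5.05 CPM. PAX2 reached 215 ± 11.4 CPM against 2.44 ± 0.865 in vehicle (6.45 log2), and CDH23 2078 ± 86.8 against 67.8 ± 5.82 CPM. EZH2 fell from 174 ± 9.68 to 60.0 ± 2.44 CPM (-1.54 ± 0.05 log2, edgeR adjusted p = 2.52e-12). In all, 5059 genes rose and 4992 fell, of which 2467 and 1365 at least 2-fold. With library totals in place of TMM 5577 of 10025 called genes (55.6%) rose, and among genes at 10 CPM or more in vehicle the 2-fold split turned, with 615 risers and 1030 fallers.

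Several of the genes with the largest rises at day 12 had no read in any day 12 vehicle library, so their change is a lower bound on a floor of 3 reads per library. COL19A1 reached 29.1 ± 2.33 CPM, at least 157-fold higher. GDF1, a TGF-beta family ligand gene that overlaps CERS1, was at least 84.3-fold higher, the phosphatase gene PPM1J at least 76.0-fold and the proton-sensing receptor gene GPR4 at least 61.7-fold. PTPRQ, a phosphatase of hair cell stereocilia, was at least 44.0-fold higher and the potassium channel gene KCNA10 at least 42.2-fold. NALCN, GPR142 and CFAP77, a gene of ciliary axonemes, were at least 37.7-, 37.2- and 37.2-fold higher. CGA, the common alpha subunit of the pituitary glycoprotein hormones, had 1 read over the vehicle group and 28.8 ± 3.83 CPM in treated cells, a ratio of 1404 (95% counting interval 252 to 55481). ADAMTSL1 was at least 136-fold higher, with summed reads at 1.91 times the authors' level. PANK4 had the third largest fitted rise, but its summed reads held 0.314 of the authors' level, and in the authors' table its log2 fold change was 0.07.

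Among the largest falls at day 12, EGR1, an immediate early transcription factor, fell from 120.3 ± 40.3 to 6.83 ± 2.32 CPM (-4.15 ± 0.47 log2, edgeR adjusted p = 1.99e-06), and CD79B from 4.32 ± 0.748 to 0.256 ± 0.202 CPM. HMSD, KCNJ5-AS1 and COL17A1 had 3 to 5 reads over the treated group, with vehicle to treated ratios of 42.7 (95% counting interval 16.3 to 159), 25.0 (95% counting interval 10.4 to 78.7) and 22.2 (95% counting interval 7.23 to 111). KCNJ5-AS1 lies antisense to KCNJ5 and may share its reads. TERT, the telomerase catalytic subunit gene, had a vehicle to treated ratio of 20.2 (95% counting interval 9.52 to 51.4), from 0.524 of the authors' level. In the authors' table its log2 fold change was -4.62. Several other falls were of genes summed in part. RRM2 of nucleotide synthesis, UHRF1 of maintenance DNA methylation, FANCD2 of crosslink repair and POLR3G had fitted log2 fold changes of -4.50, -4.23, -4.78 and -5.19. Their summed reads stood at 0.360, 0.350, 0.735 and 0.472 of the authors' level, and the authors' table gave -2.44, -2.25, -2.13 and -1.37. HSPA1B had no read in treated cells, while the authors' table gave a log2 fold change of 0.53. RPS26P19, a pseudogene of an abundant ribosomal protein gene, was at least 16.6-fold lower and may share reads with its parent.

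Proliferation genes fell without exception at day 12. Of 55 tested 0 rose and 55 fell (as many adjusted over the list alone), with a median log2 fold change of -2.13 (camera adjusted p = 7.02e-84, adjusted p = 0.00212 with an estimated correlation). The helicase gene MCM3 fell by 1.83 on the log2 scale. Of 13 cell cycle inhibitor genes 7 rose and 5 fell (as many adjusted over the list alone) (camera adjusted p = 0.514). CDKN1C reached 367 ± 21.6 CPM against 12.9 ± 3.01 in vehicle and CDKN1A 187 ± 6.98 against 50.6 ± 2.06, while CDKN2C fell by 1.63 and RBL1 by 1.63 on the log2 scale. Of 32 p53 target genes 11 rose and 9 fell (as many adjusted over the list alone), with BTG2 up by 0.81 and DDB2 down, at -1.38 log2. Of 26 BCL2 family and caspase genes 11 rose and 5 fell (as many adjusted over the list alone). BCL2 fell from 175 ± 6.87 to 43.0 ± 1.55 CPM, while HRK rose from 7.72 ± 0.342 to 96.2 ± 4.47 and BCL2L1, another survival factor, from 339 ± 30.0 to 645 ± 7.04 CPM.

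**Figure D2:**
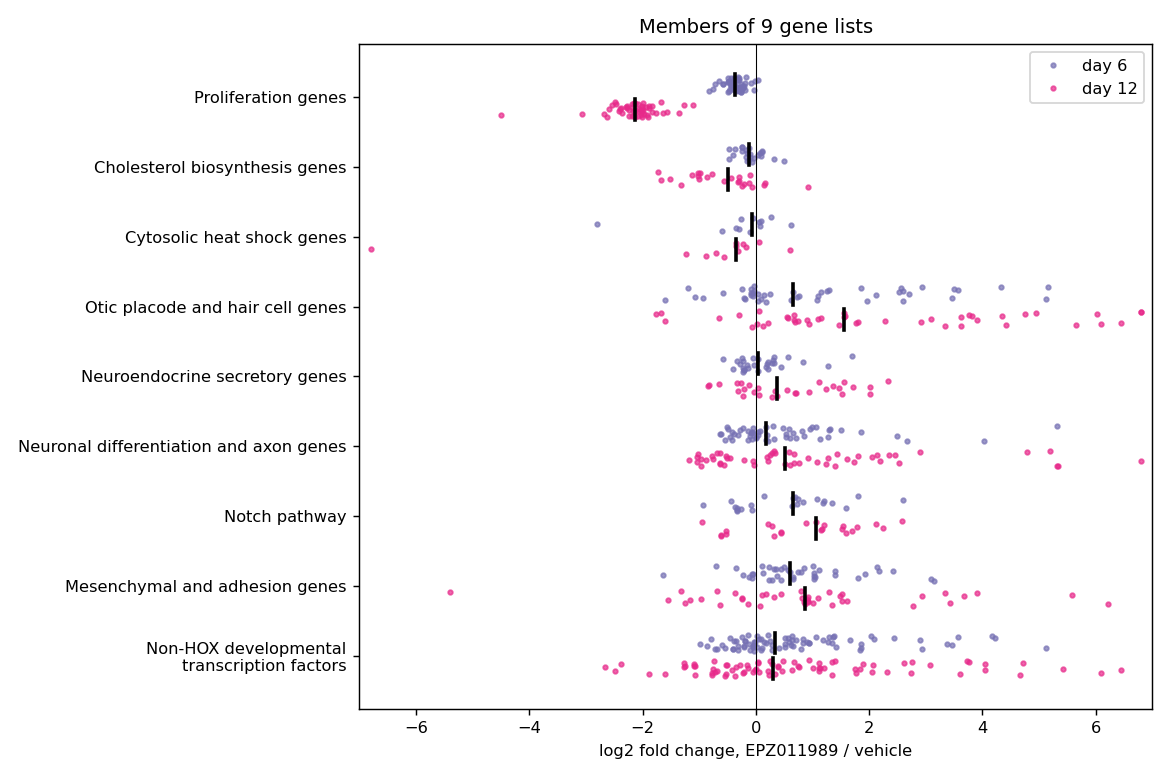
Log2 fold changes of EPZ011989 against vehicle for the tested members of 9 gene lists. Of the 30 lists fixed beforehand, these are the ones that passed camera at day 6 or day 12. Points are genes, at day 6 or day 12, black bars are list medians, and values beyond 6.8 are drawn at the edge. The proliferation median moved from -0.36 at day 6 to -2.13 at day 12, and the otic and hair cell median from 0.66 to 1.56.

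Otic placode and hair cell genes rose as a group at day 12 too. Of 45 tested 33 rose and 5 fell (34 and 5 adjusted over the list alone), with a median of 1.56 log2 (camera adjusted p = 4.88e-15, adjusted p = 0.0129 with an estimated correlation). MYO6, an unconventional myosin of hair cells that other cells also express, rose from 368 ± 17.6 to 1782 ± 61.3 CPM. The fallers included COCH (-1.76), CALB2 (-1.68) and MYO3A (-1.60 log2), and ATOH1 (0.05) and POU4F3 (0.02) did not pass edgeR. As at day 6, the otic list was not set against genes of like vehicle expression. Of 29 neuroendocrine secretory genes 16 rose and 7 fell (as many adjusted over the list alone) (camera adjusted p = 6.10e-04, adjusted p = 0.0607 with an estimated correlation). CADPS rose by 2.33, the prohormone convertase gene PCSK2 by 1.71, RAB3B by 1.23 and the granin gene CHGB by 1.55 log2. Of 53 neuronal and axon genes 31 rose and 16 fell (as many adjusted over the list alone) (camera adjusted p = 0.0249, adjusted p = 0.172 with an estimated correlation), with CNTN2 at 2.90 ± 0.06, TUBB2B at 5.32 ± 0.15 and NRXN3 at 2.19 ± 0.07 log2. Of 25 Merkel cell markers and lineage factors 9 rose and 11 fell (as many adjusted over the list alone) (camera adjusted p = 0.884). SSTR2 rose by 2.02, TUBB3 by 1.40 and MYCL by 1.64 log2, while the keratin gene KRT19 fell by 2.11.

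Notch pathway genes and mesenchymal and adhesion genes again leaned upward. Of 23 Notch pathway genes 15 rose and 4 fell (as many adjusted over the list alone) (camera adjusted p = 0.0384, adjusted p = 0.379 with an estimated correlation), with NOTCH2 at 1.59 ± 0.05 and the ligand genes JAG2 and DLL3 at 1.14 ± 0.07 and 1.07 ± 0.10 log2. Of 41 mesenchymal and adhesion genes 21 rose and 6 fell (as many adjusted over the list alone) (camera adjusted p = 0.0384, adjusted p = 0.329 with an estimated correlation). TNC rose from 23.0 ± 4.54 to 1707 ± 111 CPM and COL6A1 by 2.94 log2, while LAMB1 fell by 1.55 and ITGB1 by 0.97. Of 24 cholesterol synthesis genes 1 rose and 17 fell (as many adjusted over the list alone) (camera adjusted p = 5.59e-05, adjusted p = 0.156 with an estimated correlation). INSIG1 fell by 1.51, ACAT2 by 1.72 and SQLE, an early enzyme of the sterol branch, by 1.32 on the log2 scale. Of 12 cytosolic heat shock and chaperone genes 1 rose and 10 fell (as many adjusted over the list alone) (camera adjusted p = 0.0384, adjusted p = 0.329 with an estimated correlation), with the mitochondrial chaperonin gene HSPD1 falling by 1.24 and HSPB1 by 0.70 on the log2 scale. HSPA1B, among the fallers, is summed in part. Over completely summed genes the heat shock list had 9 fallers of 11.

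Polycomb genes themselves changed at day 12 without passing as lists. Of 13 PRC2 genes 2 rose and 7 fell (2 and 8 adjusted over the list alone) (camera adjusted p = 0.103). SUZ12 was at -0.80 ± 0.08, EED at -0.43 ± 0.16, RBBP7 at -1.10 ± 0.05 and PHF19 at -1.53 ± 0.09 log2, whereas EZH1 (0.36 ± 0.08) and JARID2 (1.42 ± 0.05) rose. Of 24 PRC1 genes 10 rose and 8 fell (as many adjusted over the list alone), with RYBP at 1.01 and KDM2B at -1.07 log2. Of 16 other chromatin regulators 4 rose and 7 fell (as many adjusted over the list alone), with NSD2 at -1.55 and the H3K27 demethylase gene KDM6B at 1.32 log2. Of 26 HOX genes 9 rose and 7 fell (as many adjusted over the list alone), with HOXC13 at 3.31 and HOXA10 at -0.74, and of 80 other developmental transcription factors 36 rose and 25 fell (as many adjusted over the list alone) (camera adjusted p = 0.280), with SIX4 at 2.74 and TFAP2B at -1.07 log2. Of 33 Wnt pathway genes 17 rose and 7 fell (as many adjusted over the list alone) and of 29 TGF-beta and BMP genes 13 rose and 9 fell (as many adjusted over the list alone), with WNT9A at 4.50 and BMP7 at -2.45 log2.

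Immune genes and markers of other cell types gave no list call at day 12. Of 18 MHC class I presentation genes 5 rose and 5 fell (as many adjusted over the list alone), but of the 12 completely summed ones 2 rose and 5 fell. The risers HLA-B and PSMB8 held 0.00834 and 0.433 of the authors' level. TAP1 rose by 1.91 log2, and HLA-C, which shares reads with its paralogues and held 0.326 of the authors' level, by 0.87 (0.88 in the authors' table). Of 5 class II genes 2 rose and 0 fell (as many adjusted over the list alone), namely HLA-DQB1 and IFI30. HLA-DQB1 went from 0.225 ± 0.0321 to 3.78 ± 0.441 CPM. IFI30 stood at 1.76 ± 0.617 CPM in treated cells and 0.0215 ± 0.0372 in vehicle, where its level at day 6 had been 1.39 ± 0.409 CPM. Of 26 interferon response genes 5 rose and 9 fell (5 and 8 adjusted over the list alone), with OAS3 at -1.32 and EIF2AK2 at -0.91 log2, and of 9 NK and T cell ligands 4 rose and 2 fell (as many adjusted over the list alone), with LGALS9 at 2.17 log2. In the stress response list 9 rose and 10 fell (as many adjusted over the list alone) of 26, PSAT1 and ATF3 rising by 2.41 and 2.01 log2. Of 13 mitochondrially encoded mRNAs 1 rose and 11 fell (as many adjusted over the list alone). Of 6 fibroblast markers 2 rose and 0 fell (1 and 0 adjusted over the list alone), of 6 leukocyte markers 0 rose and 3 fell (as many adjusted over the list alone), of 5 endothelial markers 2 rose and 1 fell (as many adjusted over the list alone) and of 7 keratinocyte markers 2 rose and 3 fell (as many adjusted over the list alone). COL1A1 stood at 4.72 ± 0.833 CPM in treated cells against 0.316 ± 0.239 in vehicle, but at 2.25 ± 0.978 in vehicle at day 6, so the day 12 contrasts of COL1A1 and IFI30 include a fall in vehicle. ITGA6 stood at 12.1 ± 1.92 CPM in treated cells against 2.27 ± 0.363 in vehicle at day 12. Of the 4 cancer-testis genes 1 rose and 1 fell (as many adjusted over the list alone), TDRD1 at 1.14 and PRAME at -1.73 log2. Without replicate 1 of the vehicle group 1 NK and T cell ligand and 0 endothelial markers fell, while 0 cancer-testis genes and 2 cholesterol synthesis genes rose. Median and mean differed in sign for HOX genes (-0.02 against 0.51), Merkel cell markers (-0.03 against 0.03), interferon response genes (-0.31 against 0.01), NK and T cell ligands (-0.00156 against 0.59) and the stress response list (-0.03 against 0.13). The TGF-beta and BMP list had a positive median and mean (0.38 against 0.57) and the keratinocyte list negative ones (-0.13 against -0.02), each opposite to camera's direction.

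The day 12 counts come from the same edgeR test over the same 15024 genes. The 8 lists past the threshold became 2, the proliferation and otic lists, with an estimated correlation, and 5 without replicate 1 of the vehicle group or without replicate 3 of the treated group.

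The day 6 and day 12 effects were then set against each other. Of the genes called at both days, 1977 rose at both and 1856 fell at both, where independent lists of these sizes would share 867 and 849.9. A further 388 were called in opposite directions. The 2 comparisons share no library, but they share 1 estimate of the spread and 1 cell line. A gene that is easy to call at 1 day may be so at the other, so the expected overlap is only a reference. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.596 and a Spearman rho of 0.546. Of the genes called in the same direction, 83.1% had the larger fitted change at day 12. The count of 3833 genes changed the same way became 2501 with transcript lengths as an offset.

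**Figure D3:**
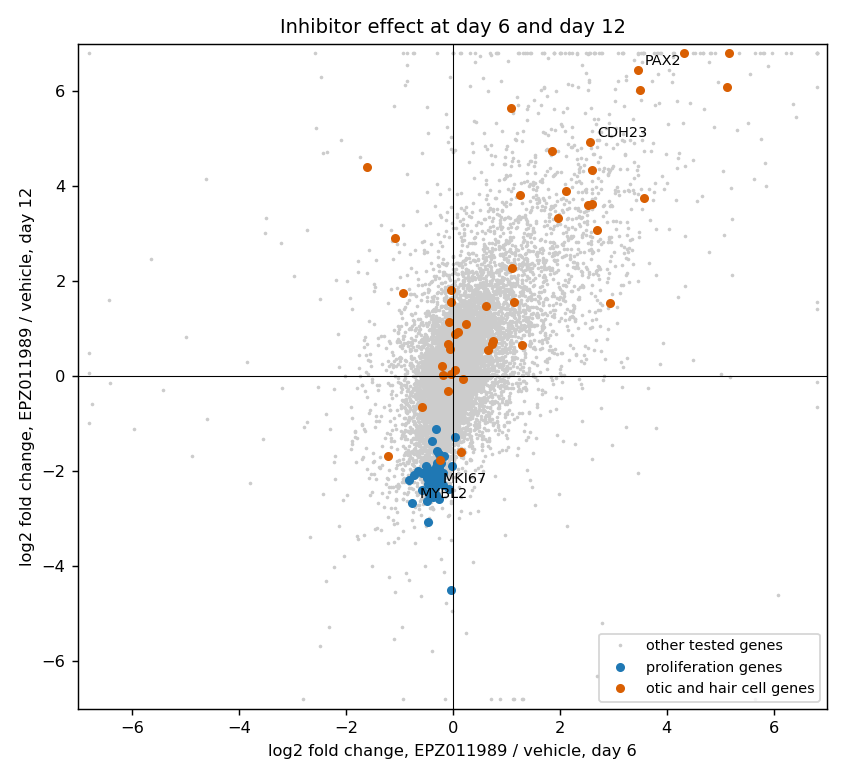
Log2 fold change of EPZ011989 against vehicle at day 6 (horizontal) and day 12 (vertical) for the 15024 tested genes, each point a gene, with values beyond 6.8 drawn at the edge. Proliferation genes lie close to 0 at day 6 and far below 0 at day 12, with medians of -0.36 and -2.13, and otic and hair cell genes extend to the upper right, with PAX2 at 3.45 and 6.45.

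The treatment effects at day 6 and day 12 were also tested for a difference, in which a more positive effect can be a larger rise, a smaller fall or a turn of direction. At day 12, 3401 genes had a more positive and 3765 a more negative effect than at day 6 (edgeR interaction contrast), but with library totals in place of TMM 3622 of 7151 were more positive, so the balance of the directions depends on the scaling. Proliferation genes shifted most as a list, all 55 with a more negative effect and a median difference of -1.75 log2 (camera adjusted p = 1.37e-105, adjusted p = 0.00157 with an estimated correlation). Otic and hair cell genes shifted upward, 23 of 45 having a more positive and 5 a more negative effect (camera adjusted p = 1.39e-07, adjusted p = 0.0440 with an estimated correlation), and so did neuroendocrine secretory genes, 16 and 6 of 29 (camera adjusted p = 1.76e-04, adjusted p = 0.0440 with an estimated correlation). Cholesterol synthesis genes (14 of 24 more negative, camera adjusted p = 4.56e-06, adjusted p = 0.106 with an estimated correlation) and heat shock genes (8 of 12, camera adjusted p = 0.0398, adjusted p = 0.330 with an estimated correlation) shifted downward. In vehicle alone 7 of the 12 heat shock genes rose and 1 fell between the days, with a median of 0.27 log2. The day 12 contrast of this list and its difference between days therefore include a rise in vehicle. Among single genes, PTPRQ stood at 0.0712 and 0.0816 CPM at day 6 and at 0 and 8.13 CPM at day 12 in vehicle and treated cells (edgeR adjusted p = 0.00230 for the difference). KCNA10 went from 0.379 CPM in treated cells at day 6 to 7.80 at day 12, the inducible chaperone gene HSPA6 from 0.101 to 4.98 and the endocytic adaptor gene EPN3 from 0.0962 to 1.99 CPM.

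The last comparison took the vehicle cells alone and asked what changed between day 6 and day 12 in culture. It called 896 genes higher and 1074 lower at day 12 (edgeR), but only 85 of them by at least 2-fold. With DESeq2 size factors 1050 of 2047 were higher, so this balance turns with the scaling. COL1A1, the main fibrillar collagen gene, went from 2.25 ± 0.978 to 0.316 ± 0.239 CPM (-2.83 ± 0.50 log2), the sterol transporter gene ABCG1 from 6.90 ± 0.862 to 1.98 ± 1.05 and COL12A1 from 1.25 ± 0.306 to 0.222 ± 0.0816 CPM. IFI30, a lysosomal thiol reductase gene, had 1 read over the day 12 group, with a day 6 to day 12 ratio of 67.9 (95% counting interval 11.8 to 2716). The stem cell surface gene PROM1 rose from 0.581 ± 0.277 to 1.75 ± 0.588 CPM. SYS1-DBNDD2, a readthrough locus, and the pseudogene TDH had log2 differences of -3.20 and -2.09. The pseudogene H3P6 (2.33 log2) may share reads with its parent. POLR3G, ALPK1 and PMS2P10 also passed the rule as risers, but their summed reads stood at 0.472, 0.503 and 3.06 times the authors' level. In the authors' table their log2 differences were 0.09, 0.55 and -0.54.

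Among the lists, 6 passed camera in vehicle between the days and 0 did with an estimated correlation. Of 12 heat shock genes 7 rose and 1 fell (9 and 1 adjusted over the list alone) (camera adjusted p = 9.72e-07, adjusted p = 0.108 with an estimated correlation), and of 24 cholesterol synthesis genes 0 rose and 10 fell (0 and 12 adjusted over the list alone) (camera adjusted p = 3.96e-06, adjusted p = 0.202 with an estimated correlation). Of 26 stress response genes 3 rose and 9 fell (4 and 11 adjusted over the list alone) (camera adjusted p = 0.00359, adjusted p = 0.378 with an estimated correlation), and of 13 mitochondrially encoded mRNAs 1 rose and 0 fell (4 and 0 adjusted over the list alone) (camera adjusted p = 0.00359, adjusted p = 0.571 with an estimated correlation). Of 25 Merkel cell markers 0 rose and 6 fell (1 and 9 adjusted over the list alone) (camera adjusted p = 0.0174, adjusted p = 0.470 with an estimated correlation), and of 6 fibroblast markers 0 rose and 2 fell (0 and 3 adjusted over the list alone) (camera adjusted p = 0.0174, adjusted p = 0.378 with an estimated correlation). Of 55 proliferation genes 9 rose and 4 fell (12 and 6 adjusted over the list alone) (camera adjusted p = 0.408). Without replicate 1 of the day 12 vehicle group 6 cholesterol synthesis genes, 5 stress response genes, 2 Merkel cell markers and 1 fibroblast marker fell, 0 mitochondrially encoded mRNAs rose, and of the proliferation genes 1 rose and 3 fell. The count of 1970 genes is unstable. It was 9 when only the 6 vehicle libraries were fitted, 142 in the authors' table with limma, and 89 with transcript lengths as an offset. Leaving out replicate 2 or 3 of the day 6 group gave 184 and 186, and leaving out replicate 1, 2 or 3 of the day 12 group 529, 470 and 4183.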

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

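The tests of the 2-fold split at higher expression and about the median gene, and the sorting of the other splits by the libraries they parted, were chosen after the results were seen, and the others here were fixed before.

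The treatment effect differed between days for 7166 of 15024 tested genes (47.7%) by edgeR's interaction contrast. It differed for 142 of the 213 genes named at either day, but most of these were chosen for a large change or a small p at a single day, so their share is no separate evidence. Further, 5 lists differed by camera in the same contrast, and 3 with an estimated correlation, under which cholesterol synthesis genes (adjusted p = 0.106) and heat shock genes (adjusted p = 0.330) lost the call. The median log2 difference, day 12 minus day 6, was -1.75 for proliferation genes, 0.86 for otic and hair cell genes, 0.48 for neuroendocrine secretory genes, -0.40 for cholesterol synthesis genes and -0.33 for heat shock genes.

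The genes with the largest fitted differences often had a group without reads, so only the edgeR adjusted p of the difference is given for these. It was 3.83e-05 for HSPA6, 0.00103 for KCNA10, 0.00160 for EPN3, 0.00230 for PTPRQ, 0.00186 for PANK4, 0.00602 for RPS26P19, 0.0144 for the pseudogene IKBKGP1, 0.0204 for CD44, 0.0304 for IL1B and 0.0426 for HSPA1B. POLR3G and FANCD2 had log2 differences of -7.98 and -4.65. PANK4, HSPA1B, POLR3G and FANCD2 are summed in part, and RPS26P19 and IKBKGP1 are pseudogenes that share sequence with a parent.

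Reads in transcripts with no matched gene, which no comparison uses, made up 3.57 ± 0.0169% in treated libraries at day 12 and 3.12 ± 0.0381% in vehicle (SD, 3 libraries each).

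Among genes changed at least 2-fold, 91.1% rose at day 6 and 64.4% at day 12. The other scalings moved genes upward and so do not test scaling (lower share 91.2% and 64.8%), but a scaling error shifts all genes alike and is argued against, since of all tested genes at least 2-fold from the median gene 85.8% lay above it at day 6 (exact 95% interval 84.0 to 87.4) and 63.1% at day 12 (61.6 to 64.6). The intervals of this paragraph count genes as independent, which they are not. They are therefore too narrow and do not measure the spread between libraries. Genes near the floor can rise but hardly fall, and among genes at 10 CPM or more in vehicle, a choice that leaves out low genes that rose, 79.1% still rose at day 6 (interval 72.6 to 84.7), which argues against the floor as the whole cause there. At day 12 the share was 37.4% (35.0 to 39.8), and with a mean of 10 CPM or more over all libraries, which low genes can pass by rising, it was 47.1% (44.9 to 49.4, and 91.4% at day 6), so the floor may account for the excess of risers at day 12. Of the 2-fold risers at day 12, 39.8% had under 1 CPM in vehicle, against 13.4% of all genes. The cuts remove many such genes whether or not their rise is real, so they do not tell a floor from a release of silent genes. As a hypothesis, release of silenced genes by the inhibitor may account for the day 6 excess, and no mark of H3K27 was measured here to test it.

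Other splits of the libraries were refitted with the same tests. For the single-day and vehicle contrasts 10 splits are too few for a share under 0.05. The real split gave 5133 genes at day 6, 10051 at day 12 and 1970 in vehicle, and the highest of the other splits 0, 1 and 1. For gene lists, 3 of 10 splits at day 6, the real one included, gave at least the real 6, up to 8. At day 12, 2 of 10, the real one included, gave at least the real 8, up to 9. Each other split put treated and vehicle libraries on both sides in unequal numbers, so part of the treatment effect remained in it. These splits therefore do not show whether the list counts exceed chance. For genes changed the same way at both days, 1 of 100 splits, the real one, gave as many as 3833. The highest other gave 388, a split with the treatment labels exchanged at a single day. The remaining splits mixed treated and vehicle libraries at 1 or both days, where almost no gene is called, and all gave 0. They restate the single-day calls, so they do not show whether chance can be excluded for this count. For the difference between days, 1 of 100 splits, the real one, gave as many as 7166 and the highest other gave 7039, a split with the day labels exchanged in vehicle alone. The 13 drawn splits that kept the treated libraries parted by day and mixed the vehicle libraries gave 5377 to 6864, while those that parted only the vehicle libraries by day gave at most 1. The count of genes therefore rests mainly on the difference between treated libraries of day 6 and day 12, and these splits do not show whether chance can be excluded for a difference of treatment effects.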

How the results depend on the processing

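The restriction to completely summed genes was chosen after the data were seen, and the other alternatives here were fixed before. Counts are genes or lists past an adjusted p of 0.05. The cause of a change was not tested unless it is given. With a fold limit of 2, which keeps fewer genes by construction, the counts were 1171 at day 6, 3832 at day 12, 2256 for the difference between days, 85 in vehicle and 922 the same way at both days. An adjusted p under 0.01 gave 3402 at day 6 and 181 in vehicle. Transcript lengths as an offset gave 3238 at day 6, 89 in vehicle and 2501 the same way at both days. In vehicle, 9 genes were called with only the 6 libraries, and 142 and 138 by limma on the authors' table with pseudocounts of 1 and 5. The other alternatives stayed within 1.5 times for these counts, apart from left-out libraries. Completely summed genes alone gave 4969 at day 6 and 9477 at day 12.

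The 6 lists at day 6 became 1 with an estimated correlation and 23 with fry, and the 8 at day 12 became 2 and 24. Fry does not compare a list with other genes. Leaving out 1 library gave 3887 to 4494 genes at day 6, 9464 to 10084 at day 12, 6505 to 7588 for the difference between days and 184 to 4183 in vehicle. For lists it gave 6 to 7 at day 6 and 5 to 8 at day 12, with 5 without replicate 1 of the vehicle group or replicate 3 of the treated group. In vehicle, the values without replicates 1, 2 and 3 of day 6 were 1834, 184 and 186, and of day 12 529, 470 and 4183.

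Same-numbered vehicle and treated libraries did not deviate together, with correlations of -0.0492 to -0.0192 at day 6 and -0.0233 to 0.0574 at day 12. These values give no sign that the numbers pair the samples, but they cannot exclude it. Vehicle libraries correlated best with the treated library of their own number in 0 of 3 cases at day 6 and 1 of 3 at day 12. Between vehicle libraries of day 6 and day 12, same-numbered correlations were 0.0946, 0.00613 and 0.0469. There, day 6 replicates 1 and 3 correlated best with their own number, and replicate 2 with number 3 (0.0943). With a replicate block the counts were 5169, 10047, 7161 for the difference and 2365 in vehicle, with 3837 the same way at both days and 7 and 8 lists.

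Of the values of named genes under all alternatives, 4967 kept direction and side of the threshold, 239 lost the call, 10 gained one and 21 changed sign. The log2 fold change of HSPA1B, summed in part, was 0.53 and 0.52 at day 12 and 0.72 and 0.72 for the difference in the authors' table, and -8.07 to 0.0245 for the difference with 1 library left out. PMS2P10 in vehicle was -0.54 and -0.25 in the authors' table. MMP2 at day 12 was -0.79 with transcript lengths and -0.46 and -0.44 in the authors' table, and VWF at day 6 -0.75 and -0.43. MAEL at day 6 was 0.00137 with the block. With 1 library left out, CD74 at day 6 ranged over -0.40 to 0.52, MAEL over -0.39 to 0.61 at day 6 and -1.13 to 0.34 at day 12, VWF at day 6 over -0.46 to 2.04 and ESAM at day 12 over -0.0498 to 0.35. Depth limits genes under about 0.194 CPM, where a group holds fewer than 3 reads per library.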

Other observations

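The lists of motile cilium, immunoglobulin and DNA repair genes, the tests of neighbouring genes and the tests of the immunoglobulin genes were chosen after the values were seen.

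Most tested genes of motile cilia rose at day 12. Of 47 tested, 39 rose and 2 fell by edgeR, against 13 and 0 at day 6. Over all 15024 tested genes 5059 rose and 4992 fell at day 12. Some members had few or no reads outside the treated day 12 group and were tested because of their reads there. Examples are ARMC3 (0.0187 CPM in vehicle and 16.3 in treated cells at day 12) and CFAP77 (0 and 6.87 CPM). Such genes could hardly be called as fallers, so the split follows in part from the low-count filter. FOXJ1, the transcription factor that directs motile cilium genes, went from 1.37 to 37.6 CPM (4.76 ± 0.19 log2) and CFAP70 from 4.39 to 83.4 CPM. HYDIN, of the central pair apparatus, went from 0.311 to 23.4 and CCDC40 from 10.3 to 111 CPM. The fallers were the dynein gene DNAH3 (-2.78 log2) and MNS1 (-1.42).

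Of 27 homologous recombination and Fanconi pathway genes, 0 rose and 18 fell at day 6, and 1 rose and 25 fell at day 12. The riser was FANCE (0.22 ± 0.09 log2, edgeR adjusted p = 0.0449). The helicase gene BLM went from 76.9 to 12.9 CPM at day 12 and FANCI from 320.2 to 66.0 CPM.

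Of the tested immunoglobulin heavy chain genes, IGHM went from 239.6 to 44.6 CPM at day 12, and IGHG1 from 161 to 46.1 CPM. Movement of reads between IGHG copies is argued against, since IGHG1 to IGHG4 summed had a treated to vehicle ratio of 0.227. Loss of a few B cells is argued against too, since light chain genes with CD74, PTPRC and MS4A1 summed to 0.346% of IGHM in vehicle. A fall of transcription from the locus within the tumour cells stays a hypothesis.

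Raised genes lay next to each other in the genome more often than shuffled ones. At day 12, 582 pairs of adjacent protein-coding genes were both raised at least 2-fold, against 394 ± 15.9 when raised genes were shuffled within deciles of vehicle expression, which argues against expression level as the cause (permutation p = 0.0001, the smallest that 10000 shuffles can give). Without overlapping or same-stem pairs 449 such pairs were found, against 289 ± 14.4 shuffled, which argues against shared reads. Runs included OTOGL, PTPRQ, LIN7A, ACSS3 and PPFIA2 on chromosome 12 (80099537 to 81759553) and HOXD13, HOXD11, HOXD10 and HOXD9 on chromosome 2 (176092891 to 176124937). The HOXD genes share a name stem, so the second count leaves their pairs out. The longest run held 6 genes, from MYORG to RPP25L on chromosome 9 (34366670 to 34612104), and no single run was tested. Genes that fell were not tested in this way, so adjacency is not shown to be particular to raised genes. A candidate explanation, as a hypothesis, is release of shared repressed domains, which may be tested with H3K27me3 maps that were not analysed here.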
